A study of Bos taurus with 20 samples.

How the data were processed

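RNA was sequenced from 20 samples of bovine embryos recovered at day 14: 6 fresh whole embryos, 5 samples of trophectoderm (TE) from fresh embryos, 2 vitrified whole embryos and 7 samples of TE from vitrified embryos. Per the submitters' processing notes, the tools were FastQC, STAR 2.5.3a with the UMD3.1 assembly, and Partek. Aligner options, the counting rule and the selection of genes are not given in the sources used here. The deposited values are in RPKM (reads per kilobase and per M reads of the library, where M stands for 1000000) with an offset of 0.01 added to every value. This unit was inferred from the values. After subtraction of 0.01 and multiplication by the genomic span of the gene in kilobases, 94.4 to 95.8% of values under 1000 reads per library fell within 0.1 of a whole multiple of a single step per library, which is 1 read. The kilobases are those of the genomic span, introns included (median 16.8 kb), so levels of different genes are not comparable with values scaled to exon length. The steps gave totals of 6.01 to 14.53 M reads per library. Reads of the listed genes summed to 33.8 to 63.9% of these totals. Intervals and limits from reads cover counting error only.

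The table held 15542 genes, of which 15027 were protein coding. Names of 1819 genes were Ensembl identifiers alone, 80 were Rfam families and 20 had been turned into dates. These were tested but not named. For 4 genes every library stood at the offset. Genes with at least 10 recovered reads in at least 2 libraries were tested, which kept 10599 and left out 4943. XIST, CDX2 and IFNT2, which had been chosen for naming, were not analysed here.

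The offset was subtracted and log2(value + 1) taken. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust fitting, through statmod 1.5.0) in a model with a mean for each of the 4 groups and a spread shared by them. Contrasts were vitrified against fresh TE, vitrified against fresh whole embryos, the difference of these effects (whole embryo minus TE), and whole embryo against TE among fresh and among vitrified samples. A model with sample kind and vitrification as terms gave the effect averaged over both kinds. P-values were adjusted by the Benjamini-Hochberg method over genes within a comparison, with a threshold of 0.05. The replicate numbers were not used as pairs. The plan foresaw a test on read counts, with this limma test for normalized values. Since the values were normalized, the limma test was used and edgeR and DESeq2 were not run. Fold differences of means given in the text are ratios of mean RPKM, and a fold change from limma is a difference on the log2(value + 1) scale.

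Gene lists were fixed before the data were examined. They held 986 symbols in 28 lists, of which 839 were found, 12 of them through a synonym, and 26 lists had at least 5 tested members. The lists covered trophectoderm identity, interferon tau and early conceptus secretions, pregnancy-associated glycoproteins and the prolactin family, epiblast and pluripotency, hypoblast and yolk sac, mesoderm and gastrulation, maternal endometrium markers, blood and immune markers, interferon-stimulated genes, apoptosis and p53 targets, heat shock and endoplasmic reticulum stress, oxidative stress and metallothioneins, lipid uptake and PPAR genes, fatty acid and cholesterol synthesis, prostaglandin and steroid synthesis, junctions and epithelial adhesion, cytoskeleton, water and ion transport, nutrient transport, glycolysis and hypoxia, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, cell cycle, DNA methylation and chromatin, imprinted genes, extracellular matrix and proteases, and Wnt, TGF and FGF signalling. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01, and with an estimated correlation and fry beside it. Adjusted p are over the lists within a comparison. Members were also adjusted over the list alone. Some genes stand in more than 1 list.

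Genes named in the text followed a rule set before the data were examined. In vitrified against fresh TE, vitrified against fresh whole embryos and fresh whole embryos against fresh TE, it took the 8 highest and 8 lowest fold changes past the threshold among genes with a symbol and at least 5 RPKM in the higher group. It took from each list up to 4 members with the smallest p past the threshold, or at most 2 that did not pass, and the 5 smallest p for vitrified whole embryos against TE and for the difference of effects. It added GATA3, POU5F1, NANOG, SOX2, GATA6 and PAG2 in all groups. A gene named for a comparison was also followed in others. DDX3Y and DDX3X were chosen after their values were seen.

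Library measures (share of reads in listed genes, genes with at least 10 reads, mitochondrial messenger and ribosomal RNA, small RNA reads) were compared between groups by exact two-sided permutation tests of the difference of means, adjusted over 20 tests, with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15. Figures were drawn with matplotlib 3.10.9, and values were read in R with the data.table package, version 1.17.8.

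Alternatives chosen before the data were examined were quantile normalization, a pseudocount of 0.1, no filter, a filter of at least 5 RPKM, a fit of only the groups compared, sample weights, the replicate number as a block, leaving out each library in turn, and, for lists, an estimated correlation and fry. Chosen after seeing the data were scaling to listed-gene reads, median-ratio scaling, limma voom on recovered reads, the level of DDX3Y as a covariate, averaging near-identical fresh TE libraries, and thinning every library to about 2.03 M listed-gene reads. For lists the order differed for 2 of these settings: median-ratio scaling was planned, and the fit of only the groups compared was added afterwards. Other splits of the samples were tested for comparisons with at least 3 samples per group, and, added after the results were seen, with near-identical fresh TE libraries averaged. Vitrified whole embryo 1 was tested alone against each 6 of the 7 vitrified TE libraries, beside the remaining TE library, in the same model with single libraries as groups of their own, a test added after the results were seen.

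The procedure was tested on simulated data with 50 changed genes per fold size. For vitrified against fresh TE (10252 genes) it called 30, 70, 82 and 96% of genes changed 1.5, 2, 4 and 8-fold, with 12 calls among unchanged genes (7.9% of calls). For vitrified against fresh whole embryos (10275 genes) the percentages at the same fold sizes were 8, 36, 72 and 82, for both kinds together (10285 genes) 46, 76, 94 and 94, and for the difference of effects (10267 genes) 0, 30, 72 and 74. For whole embryo against TE they were 24, 56, 94 and 98 among fresh (10285 genes) and 0, 36, 74 and 82 among vitrified samples (10288 genes). Calls among unchanged genes made up 9.2, 6.6, 7.4, 3.5 and 5% of calls in these 5 comparisons, and no changed gene was called in the wrong direction. A raised list was called with camera at an adjusted p of 6.8e-91 and 0 of 25 other lists passed, over 10259 genes. Simulated genes varied independently of each other, without a shift of most genes and without near-identical libraries. The simulation therefore does not test list calls where genes vary together, or calls where most genes move 1 way.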

Results

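RNA sequencing profiles of 20 samples from bovine embryos at day 14 were compared. They comprised 6 fresh whole embryos, 5 samples of trophectoderm (TE) isolated from fresh embryos, 2 vitrified whole embryos and 7 samples of TE from vitrified embryos. The submitters' design counts 12 fresh and 9 vitrified embryos, recovered by flushing the uterus, and the labels do not say which embryo gave which sample. Vitrification is cryopreservation by cooling fast enough to form a glass, and fresh embryos had not been vitrified. At this stage the embryo elongates, and its TE, the outer epithelium from which the placenta arises, secretes interferon tau, the signal that maintains pregnancy in ruminants. A whole embryo holds, beside TE, the epiblast, which forms the body, and the hypoblast, which lines the yolk sac. The deposited table gave 15542 genes in RPKM (reads per kilobase and M reads, where M stands for 1000000), and whole read numbers could be recovered from it. Libraries held 6.01 to 14.53 M reads, of which 2.03 to 8.73 M lay in the listed genes. P-values measure only the spread among these samples, part of which may be technical, because the labels do not say how the samples of a group relate to each other. The labels name no batch, so a batch that follows a group cannot be told apart from that group. Fold changes in the tests are on the log2(value + 1) scale, which understates the change of low genes, and positions are on the UMD3.1 assembly.

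The 5 fresh TE libraries stood apart from the other 15. The listed genes took 38.0 ± 2.81% of their reads (SD, n = 5) and 57.5 to 63.9% in the others. Messenger RNAs encoded by mitochondria made up 1.23 ± 0.146% of listed-gene reads in fresh TE and 8.04 ± 1.44% in vitrified TE (n = 7), and 3.01 to 9.87% over the other 15 libraries. Reads of 79 small RNA genes numbered 688 ± 193 per M listed-gene reads in fresh TE and 148 ± 39.7 in vitrified TE. For each of these 3 measures the exact two-sided permutation test gave p = 0.0025 between vitrified and fresh TE (n = 7 and 5), with an adjusted p of 0.0096 over 20 tests. Mitochondrial ribosomal RNA did not part them, at 4.28 ± 0.189% in fresh TE and 4.09 ± 1.15% in vitrified TE (exact permutation p = 0.72). Across genes, rank correlations between libraries averaged 0.865 between fresh and vitrified TE, 0.943 between fresh and vitrified whole embryos, and 0.957 between vitrified TE and vitrified whole embryos. Fresh TE 1 and 2 differed from each other by little more than sampling noise (chi-square per degree of freedom 2.1), as did fresh TE 3 and 4 (1.5), whereas the other fresh TE pairs gave 14.8 to 28.8. These near-identical libraries were kept as separate samples, and averaged in an alternative for genes, lists and splits. They were not averaged in the permutation tests of library measures, here and below. Those tests count all 5 fresh TE libraries as independent, so their p may be too small. DDX3Y, a Y-linked gene chosen after its values were seen and placed by the table on chromosome X, 143364826 to 143375658, had at least 10 reads in 5 of 6 fresh whole embryos, 0 of 5 fresh TE samples, 2 of 2 vitrified whole embryos and 5 of 7 vitrified TE samples.

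**Figure D1:**
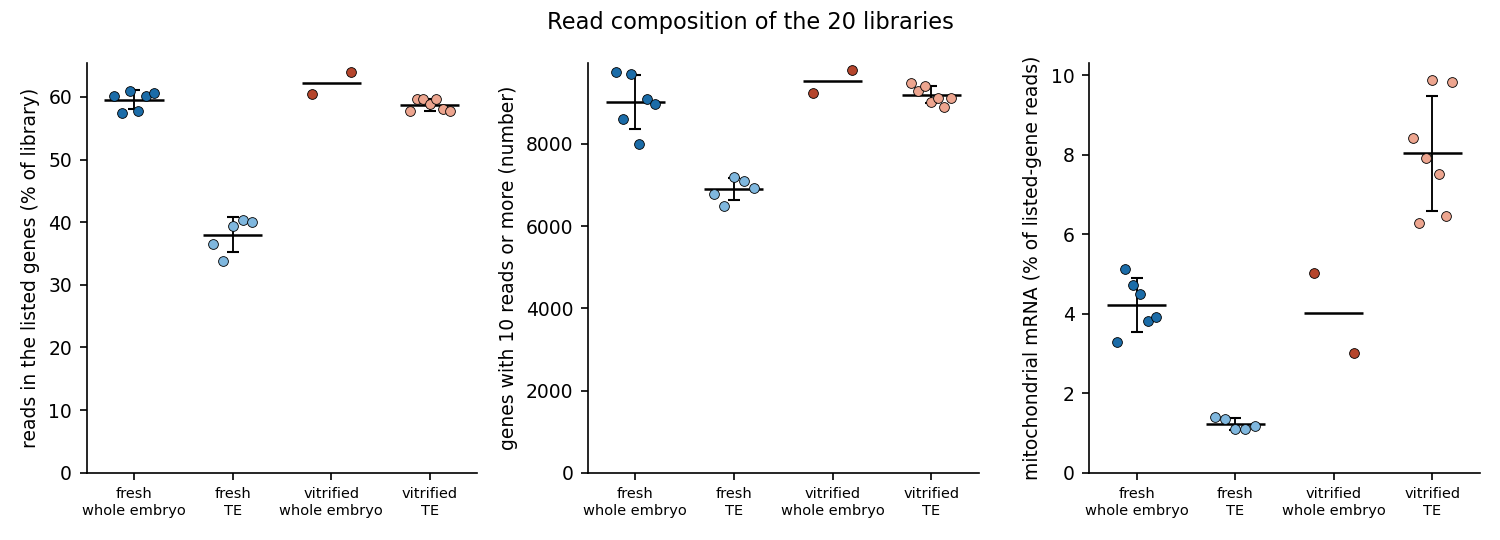
Each point is a library, grouped by sample group on the horizontal axis; the vertical axes show the percent of reads in listed genes, the number of genes with at least 10 reads, and mitochondrial messenger RNA as a percent of listed-gene reads, with a horizontal line at the group mean and bars of 1 SD for groups of more than 2. The fresh TE libraries lie at 33.8 to 40.3% of reads in listed genes, below the 57.5 to 63.9% of the other 15.

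How vitrification relates to transcript levels of the TE was addressed by the 7 vitrified and 5 fresh TE samples. These 5 are the libraries that stood apart, so differences between vitrified and fresh TE also carry whatever set them apart. Transcripts of IFNT and PAG2, 2 secreted trophoblast products, were lower in vitrified TE. IFNT, which encodes interferon tau, stood at 3.75 ± 0.959 RPKM (SD, n = 7) against 119 ± 19.9 (n = 5). This was a 31.8-fold difference of means, with every vitrified TE sample below every fresh one. PAG2, a pregnancy-associated glycoprotein, stood at 1.73 ± 0.885 against 61.5 ± 18.1 RPKM. Fresh whole embryos, which had not been vitrified and also hold TE, were far below fresh TE as well, at 12.9 RPKM of IFNT and 0.883 of PAG2. In vitrified TE the keratin gene KRT8 was higher than in fresh TE, at 859 ± 113 against 163 ± 16.9 RPKM. So was the trophoblast transcription factor ASCL2, at 136 ± 32.8 against 13.9 ± 4.30. All 13 mitochondrially encoded messenger RNAs and 35 of 42 cell cycle genes rose, while cytosolic ribosomal protein genes split into 22 higher and 35 lower.

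Of 10599 genes tested, 7311 were higher and 706 lower in vitrified TE at an adjusted p under 0.05, so that 91.2% of calls were higher. The split moved with scaling. It was 5212 higher and 1666 lower per M listed-gene reads (75.8% higher), 3732 higher and 2906 lower with median-ratio scaling (56.2%) and 2776 higher and 4100 lower with quantile normalization (40.4%). The median gene was 2.45-fold higher in vitrified TE as deposited (1.29 on the log2 scale), 1.58-fold per M listed-gene reads and 1.13-fold with median-ratio scaling. The directions of gene lists of this comparison are therefore given with the scalings under which they turned. With 7311 of 10599 genes higher, a list of mostly higher members need not differ from other genes. Among lists that did not pass with camera were trophectoderm identity and epiblast (adjusted p = 0.84 each), and apoptosis and water transport (0.98 each). Imprinted and matrix (0.56 each), heat shock (0.51) and junction genes (0.29) did not pass either.

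Among secreted products, the IFNT gene (chromosome 8, 22607643 to 22634001) fell by 4.67 on the log2 scale (adjusted p = 2.2e-12), and its means differed 49.4-fold per M listed-gene reads. PAG2 (chromosome 29, 38155711 to 38165208) fell by 4.53 and PAG11 (chromosome 29, 40130397 to 40148837) by 3.55, from 108 ± 20.1 to 9.11 ± 4.58 RPKM. Both gene families have many near-identical copies, so the copy that gave these reads is uncertain. PINLYP, a secreted phospholipase inhibitor gene (chromosome 18, 52120387 to 52124418), went from 511 ± 163 to 38.3 ± 9.20 RPKM, and PTGS2, the inducible enzyme of prostaglandin synthesis (chromosome 16, 69263776 to 69271399), from 117 ± 26.4 to 26.0 ± 7.98. Of 8 genes for interferon tau and other early secretions, 3 rose, among them SPINT1 (1.25), and 5 fell, among them SSLP1 (-1.09). Camera placed the list lower (adjusted p = 3.0e-05, and adjusted p = 0.05 with an estimated correlation). In the pregnancy-associated glycoprotein and prolactin list 3 of 4 members fell and none rose, too few for a set test.

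**Figure D2:**
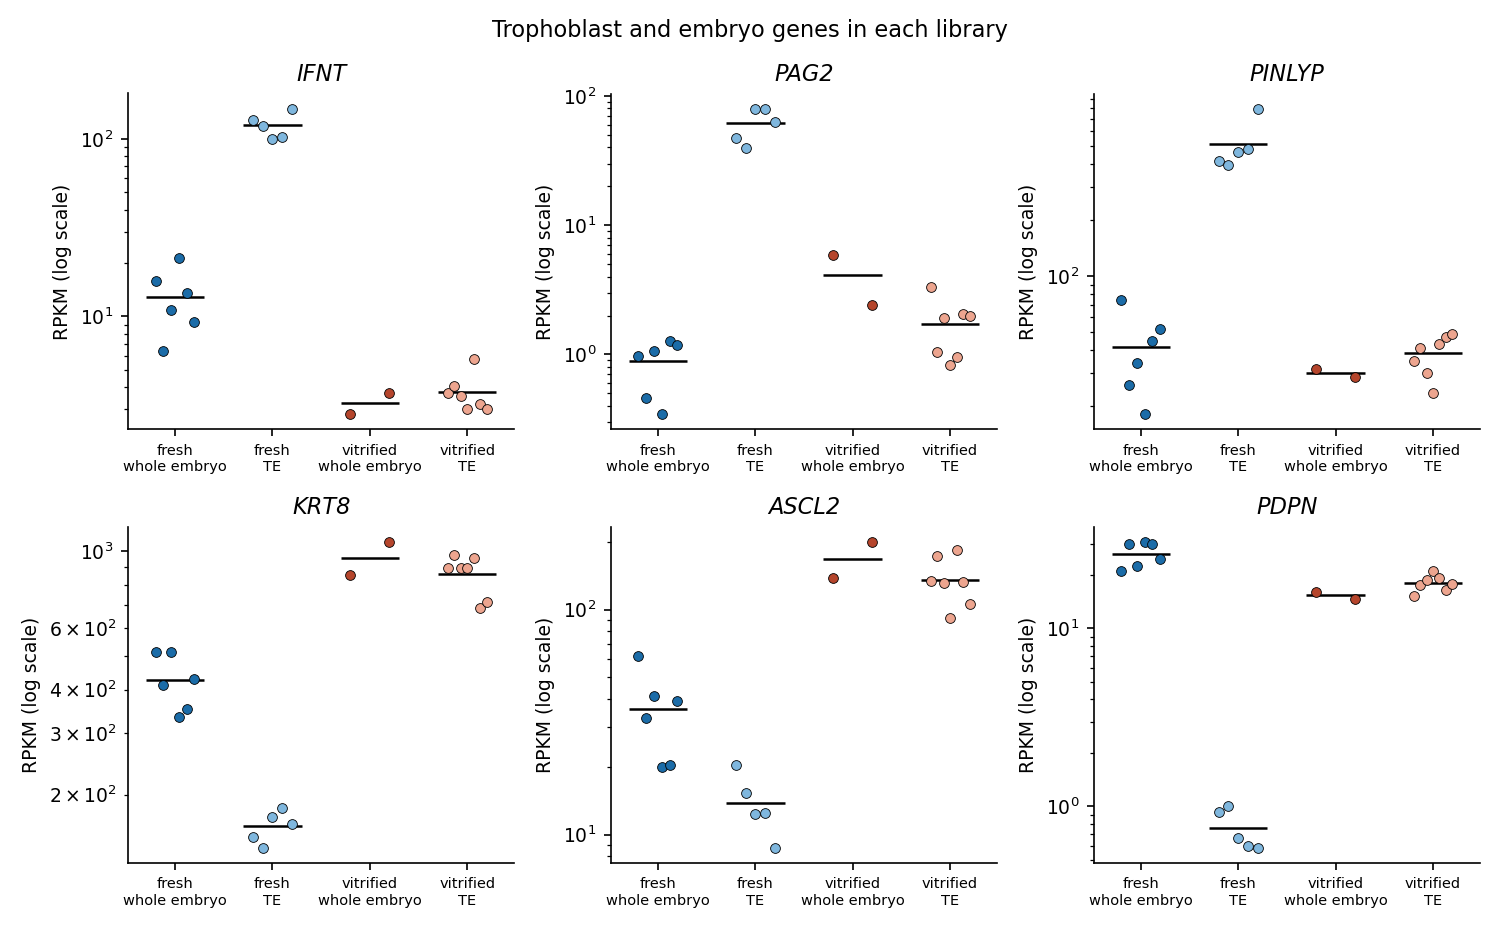
Each point is a library, with its level in RPKM on a logarithmic vertical axis and its group on the horizontal axis; a line marks the group mean for IFNT, PAG2, PINLYP, KRT8, ASCL2 and PDPN. IFNT lies at 99.9 to 148 RPKM in fresh TE and at 2.99 to 5.74 in vitrified TE, whereas KRT8 lies at 141 to 183 and 688 to 976.

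Of 19 genes of trophectoderm identity, 13 were higher, 2 lower and 4 not past the threshold (8 higher and 7 lower under quantile normalization). KRT8 (chromosome 5, 27213750 to 27221177) rose by 2.39 on the log2 scale, ID2, an inhibitor of basic helix-loop-helix factors, by 3.56, the epithelial factor ELF3 by 3.43 and ASCL2 (chromosome 29, 49955760 to 49957635) by 3.21. The trophoblast regulator GATA3 rose by 0.77 (adjusted p = 6.4e-07), from 1.35 ± 0.239 to 3.0 ± 0.381 RPKM, but stood at -0.03 under quantile normalization, with adjusted p of 4.2e-08 to 0.81 over all alternatives. Of 15 epiblast genes 8 rose and none fell. They included PDPN, a mucin-like membrane protein (chromosome 16, 55407771 to 55442826), from 0.758 ± 0.196 to 18 ± 1.89 RPKM, ZFP42 from 0.160 ± 0.103 to 24.3 ± 12.5 and the pluripotency factor KLF4 from 1.25 ± 0.370 to 6.80 ± 1.90. The core pluripotency gene POU5F1 stood at 0 to 0.113 RPKM in fresh and 0.302 to 1.25 in vitrified TE, without overlap. It did not pass in the model of 4 groups (0.77, adjusted p = 0.12), whose shared spread includes the 2 unlike vitrified whole embryos, and passed under 3 of 24 alternatives (3.4e-05 with only the groups compared, 0.0017 with a pseudocount of 0.1 and 0.023 with sample weights; up to 0.33 over the others). NANOG and SOX2 did not pass, at 0.0206 ± 0.0324 and 0.0228 ± 0.0510 RPKM in fresh and 0.0370 ± 0.0637 and 0.133 ± 0.102 in vitrified TE (adjusted p of SOX2 0.033 to 0.74 over all alternatives). Of 23 hypoblast and yolk sac genes 22 rose and 1 fell (camera adjusted p = 0.03, and adjusted p = 0.56 with an estimated correlation, towards higher). The lipid carriers APOE (4.67) and APOM (1.62) were among them, while GATA6, an early endoderm factor, rose by 0.17 from a level near 0, to 0.130 ± 0.0513 RPKM. Among mesoderm genes 4 of 5 rose, BMP4 by 1.05.

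Mitochondrial transcripts had the highest median change of the 28 lists. The 13 mitochondrially encoded genes had a median log2 change of 3.88 (camera adjusted p = 8.1e-07, and adjusted p = 0.32 with an estimated correlation), and at least 12 of them were higher under every scaling. COX1, a subunit of cytochrome oxidase (mitochondrial genome, 5687 to 7231), went from 679.6 ± 114 to 8001 ± 1288 RPKM and MT-ND4, a subunit of complex I, from 111 ± 6.28 to 2281 ± 403. Neighbouring mitochondrial genes overlap, so their shares of reads are uncertain. The same libraries held 1.23 ± 0.146% and 8.04 ± 1.44% of mitochondrial messenger RNA. Nuclear genes of oxidative phosphorylation were 28 higher, 11 lower and 9 not past the threshold as deposited and turned to 15 higher and 23 lower under quantile normalization, 18 and 21 under listed-gene scaling and 12 and 28 under median-ratio scaling. NDUFS8, of complex I, rose by 3.95, and ATP5ME, of ATP synthase, fell by 2.07, from 719 ± 51.1 to 171 ± 17.4 RPKM. Of 74 cytosolic ribosomal protein genes 22 were higher, 35 lower and 17 not past the threshold (camera adjusted p = 3.2e-14, and adjusted p = 0.35 with an estimated correlation, towards lower), and under median-ratio scaling 7 higher and 60 lower. RPL24 fell from 153 ± 3.39 to 60.2 ± 3.58 RPKM, and RPL28 rose from 53.8 ± 10.3 to 343 ± 52.2.

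**Figure D3:**
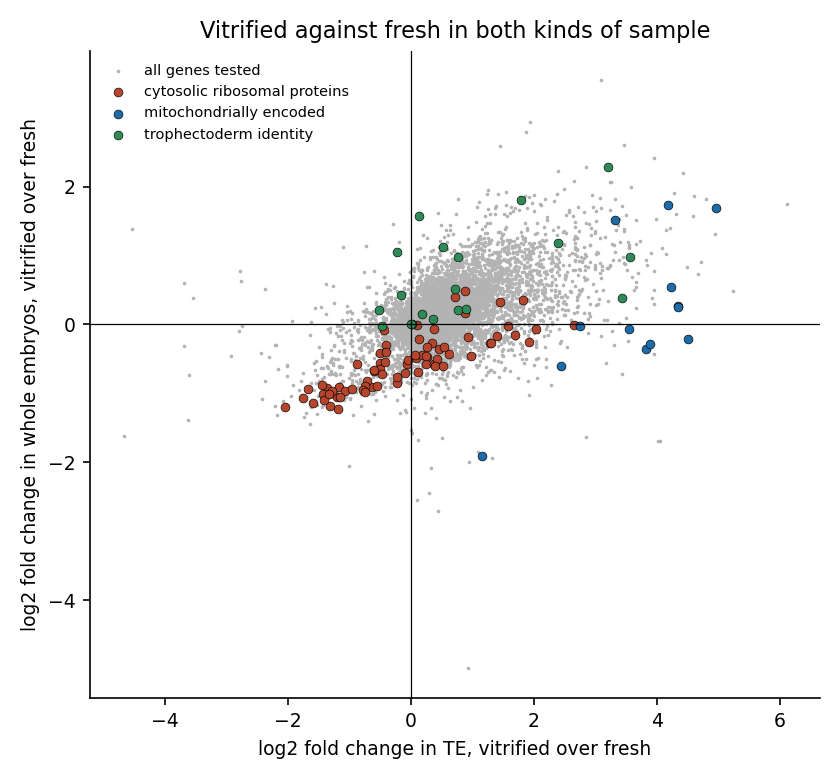
Each point is a gene, with its log2 fold change of vitrified against fresh TE on the horizontal axis and of vitrified against fresh whole embryos on the vertical axis; grey points are all 10599 genes tested, red points ribosomal protein genes, blue points mitochondrially encoded genes and green points trophectoderm identity genes. Mitochondrial genes lie far to the right at a median of 3.88 in TE and -0.03 in whole embryos, and ribosomal protein genes at -0.15 and -0.57, while as a set they were 7 higher and 60 lower in TE under median-ratio scaling.

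Of 42 cell cycle genes 35 were higher, 1 lower and 6 not past the threshold (camera adjusted p = 9.8e-04, and adjusted p = 0.44 with an estimated correlation), and with quantile normalization 22 higher and 11 lower. CDK4, a kinase of the G1 phase, rose from 2.02 ± 0.553 to 34.1 ± 4.17 RPKM and the mitotic kinesin KIF20A from 0.311 ± 0.134 to 5.47 ± 0.594. Heat shock and endoplasmic reticulum stress genes were 24 higher, 2 lower and 9 not past the threshold and turned to 12 higher and 15 lower under median-ratio scaling. PPP1R15A, a phosphatase subunit induced by stress, rose by 3.31, the stress factor DDIT3 by 2.51 and the small heat shock protein HSPB1 by 4.71, from 11.2 ± 2.90 to 313 ± 32.6 RPKM. Apoptosis and p53 target genes were 16 higher, 1 lower and 7 not past the threshold and turned to 7 higher and 11 lower under quantile normalization and 7 and 8 under median-ratio scaling. GADD45A rose by 1.96 and GADD45B by 2.38. Oxidative stress genes were 20 higher, 1 lower and 12 not past the threshold and turned to 7 higher and 10 lower under quantile normalization and 8 and 10 under median-ratio scaling, with the glutathione transferase GSTP1 up by 3.31 and the peroxiredoxin PRDX2 by 2.23. Glycolysis and hypoxia genes were 23 higher, 5 lower and 7 not past the threshold and turned to 9 higher and 15 lower under quantile normalization and 10 and 13 under median-ratio scaling. PKM rose by 3.47, GAPDH by 3.46, and NDRG1, induced by low oxygen, fell by 0.74.

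Large rises among genes outside the lists were those of TMEM88, a membrane protein of Wnt signalling (chromosome 19, 28156792 to 28157769), from 2.12 ± 0.630 to 124 ± 48.1 RPKM, and of SRM, spermidine synthase, from 1.78 ± 0.428 to 84.7 ± 12.1. Junction and adhesion genes were 26 higher, 1 lower and 9 not past the threshold and turned to 11 higher and 11 lower under quantile normalization. The tight junction gene CLDN6 rose by 4.80, and the desmosome genes JUP and DSP by 2.10 and 1.77. Of 38 cytoskeleton genes 25 were higher, 4 lower and 9 not past the threshold. PFN1, which binds actin, rose by 4.59 and TMSB10, which sequesters actin monomers, fell from 13320 ± 2238 to 3413 ± 219 RPKM. Water and ion transport genes were 11 higher, 1 lower and 4 not past the threshold, with the water channel AQP3 up by 1.75. In nutrient transport 13 of 20 rose and none fell, SLC38A2 by 2.04 and SLC3A2 by 1.87.

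Lipid genes went both ways. Lipid uptake and PPAR genes were 13 higher, 6 lower and 11 not past the threshold and turned to 5 higher and 17 lower under quantile normalization, 8 and 13 under listed-gene scaling and 5 and 16 under median-ratio scaling. Camera placed them lower relative to other genes (adjusted p = 2.3e-04, and adjusted p = 0.039 with an estimated correlation) although their median was 0.03. MOGAT1, an enzyme of triglyceride synthesis, fell from 2.91 ± 0.339 to 0.509 ± 0.128 RPKM, and the fatty acid carrier SLC27A6 from 0.517 ± 0.108 to 0.0115 ± 0.00678. Fatty acid and cholesterol synthesis genes were 11 higher, 8 lower and 13 not past the threshold and turned to 3 higher and 23 lower under quantile normalization, 8 and 16 under listed-gene scaling and 5 and 23 under median-ratio scaling, with a median of 0.03 and a camera call towards lower (adjusted p = 1.9e-04, and adjusted p = 0.25 with an estimated correlation). Without fresh TE 5 the lower members numbered 5. The elongase ELOVL1 rose by 2.99 and the desaturase FADS2 fell by 1.62. Prostaglandin and steroid synthesis genes were 6 higher, 7 lower and 6 not past the threshold, with a median of 0.01 and a camera call towards lower (adjusted p = 3.1e-04, and adjusted p = 0.039 with an estimated correlation). STAR, which moves cholesterol into mitochondria, rose by 1.08 while PTGS2 fell.

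DNA methylation and chromatin genes were 26 higher, 0 lower and 6 not past the threshold and turned to 13 higher and 13 lower under quantile normalization, with the acetyltransferase EP300 at 0.0423 ± 0.0108 and 0.687 ± 0.0608 RPKM in fresh and vitrified TE and the methyltransferase DNMT1 at 0.118 ± 0.0220 and 0.891 ± 0.0879. Of 14 imprinted genes 10 were higher, 1 lower and 3 not past the threshold, PHLDA2 rising by 2.70. Extracellular matrix and protease genes were 22 higher, 0 lower and 9 not past the threshold, the lysosomal protease CTSD rising by 2.77. Signalling genes of the Wnt, TGF and FGF pathways were 19 higher, 3 lower and 7 not past the threshold and turned to 6 higher and 9 lower under quantile normalization. BMP2 fell from 1.69 ± 0.475 to 0.203 ± 0.162 RPKM. Interferon-stimulated genes were 4 higher, 0 lower and 9 not past the threshold and turned to 2 higher and 6 lower under quantile normalization and 2 and 3 under median-ratio scaling, with IRF7 up by 1.62. Blood and immune markers, listed to detect other cells, were 4 higher, 1 lower and 2 not past the threshold and turned to 2 higher and 2 lower under quantile normalization and 2 and 2 under median-ratio scaling: CD68 stood at 0.380 ± 0.163 and 3.17 ± 1.04 RPKM, and AIF1 fell from 11.3 ± 2.5 to 0.632 ± 0.283. Of 3 markers of maternal endometrium 2 rose, SUSD2 to 4.16 ± 3.0 RPKM.

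These calls came from limma, and list calls from camera with a preset correlation of 0.01 over 26 lists. 8 lists passed, and only the lipid uptake and prostaglandin lists passed also with an estimated correlation. Adjusted over the list alone, the counts of higher and lower members were 35 and 2 for cell cycle, 11 and 7 for fatty acid synthesis, 19 and 1 for oxidative stress, 12 and 1 for water transport and 27 and 0 for chromatin genes, and those given over all genes for the other lists. With only genes of at least 5 RPKM, 2087 were tested and 1784 passed.

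Whole embryos, 2 vitrified and 6 fresh, addressed the same question for samples labelled as whole embryos. ASCL2 and KRT8 were again higher after vitrification, ASCL2 at 168 ± 43.4 RPKM (SD, n = 2) against 36.0 ± 15.7 (n = 6) and KRT8 at 957 ± 144 against 426 ± 75.9. Cytosolic ribosomal protein genes were lower, 41 of 74 with none higher, and so was IFNT, at 3.25 ± 0.614 against 12.9 ± 5.27 RPKM. Falls were also seen in CCL27, a chemokine (chromosome 8, 77368244 to 77368955), from 132 ± 58.7 to 2.80 ± 1.36 RPKM, and in the plasminogen activator PLAU (chromosome 28, 29964983 to 29971029), from 68.8 ± 22.1 to 9.75 ± 4.69. In all, 2852 genes were higher and 418 lower (87.2% higher), and with median-ratio scaling 1123 higher and 741 lower (60.2%), with quantile normalization 920 higher and 651 lower (58.6%). The median gene was 1.30-fold higher as deposited and 1.03-fold with median-ratio scaling. A group of 2 leaves 1 sample when either is left out, which is then assumed to vary like the other groups: without vitrified whole embryo 2 the count past the threshold was 1137, and without vitrified whole embryo 1 it was 3008, 235 of them lower.

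Of 19 trophectoderm identity genes 10 were higher, 0 lower and 9 not past the threshold (camera adjusted p = 0.017, and adjusted p = 0.28 with an estimated correlation), and 6 were higher without vitrified whole embryo 2. ASCL2 rose by 2.28 on the log2 scale, KRT8 by 1.18, GATA3 by 0.98 and the homeobox gene MSX2 by 1.81. The Wnt receptor FZD10 rose from 2.08 ± 1.05 to 16.8 ± 3.6 RPKM and the immediate early gene FOS from 9.56 ± 7.74 to 61.6 ± 18.8. PAG2 stood at 4.13 ± 2.42 against 0.883 ± 0.386 RPKM (1.39, adjusted p = 0.004), a call lost without vitrified whole embryo 1 (0.89, adjusted p = 0.12; 0.0028 to 0.12 over all alternatives). IFNT fell by 1.62 (adjusted p = 5.5e-04). The interferon tau list was 1 higher, 1 lower and 6 not past the threshold and turned to 1 higher and 2 lower under quantile normalization and 1 and 3 under median-ratio scaling. Camera placed it lower (adjusted p = 0.034, and adjusted p = 0.43 with an estimated correlation), a call lost without fresh whole embryo 3 (adjusted p = 0.061) or vitrified whole embryo 1 (0.14), with 0.017 to 0.43 over all alternatives. The pregnancy-associated glycoprotein list had 1 of 4 higher.

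The epiblast genes POU5F1, NANOG and SOX2 parted the vitrified whole embryos from each other, while ZFP42 (74.7 and 71.4 RPKM) and PDPN (16.0 and 14.7) were close. POU5F1, the core pluripotency factor (chromosome 23, 27769893 to 27774392), stood at 0.316 RPKM in vitrified whole embryo 1 and 20.6 in vitrified whole embryo 2, against 1.05 to 6.01 in fresh whole embryos. NANOG was listed at 0 and 4.22 RPKM (0 reads allow up to 0.0690 RPKM, counting error only), and SOX2 at 0.0813 and 2.98. No difference between groups passed for POU5F1 (0.83, adjusted p = 0.32), NANOG or SOX2. Without vitrified whole embryo 1 POU5F1 stood at 2.85 (adjusted p = 7.7e-05; 7.7e-05 to 0.75 over all alternatives), NANOG at 1.52 (adjusted p = 0.0013; 0.0013 to 0.85) and SOX2 at 1.62 (adjusted p = 2.7e-06; 2.7e-06 to 0.34). They stood at -1.18, -0.87 and -0.26 without vitrified whole embryo 2 and did not pass. Of 15 epiblast genes 5 were higher, 1 lower and 9 not past the threshold, with 8 higher without vitrified whole embryo 1 and 1 without vitrified whole embryo 2. PDPN fell by 0.73. Hypoblast genes were 3 higher, 2 lower and 18 not past the threshold and turned to 1 higher and 3 lower under quantile normalization, 2 and 3 under listed-gene scaling and 1 and 4 under median-ratio scaling (1 higher without vitrified whole embryo 2), GATA6 rising by 0.10 (adjusted p = 0.017) from a level near 0. GATA6 lost its call under median-ratio scaling (0.091) and quantile normalization (0.16), with 9.3e-04 to 0.17 over all alternatives.

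**Figure D4:**
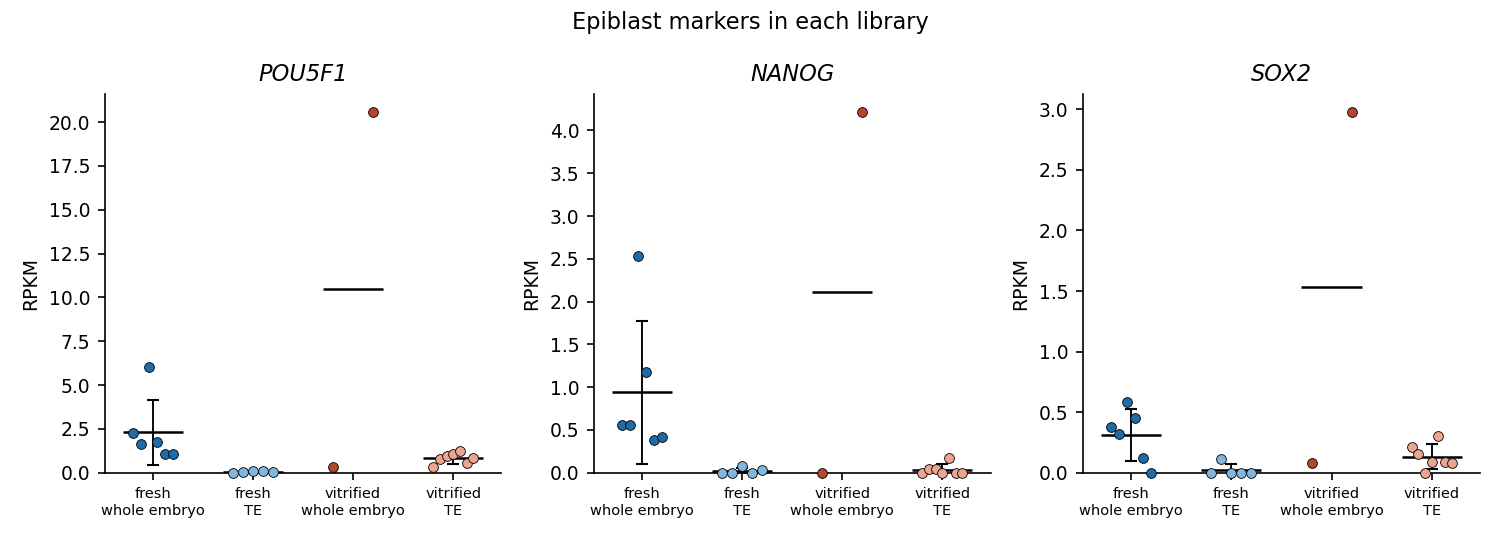
Each point is a library, with its level in RPKM on a linear vertical axis for POU5F1, NANOG and SOX2 and its group on the horizontal axis; lines mark group means and bars 1 SD for groups of more than 2. Vitrified whole embryo 2 lies at 20.6 RPKM of POU5F1, and vitrified whole embryo 1 at 0.316, within the 0.302 to 1.25 of vitrified TE.

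Camera placed ribosomal protein genes towards lower (adjusted p = 3.4e-34, and adjusted p = 0.27 with an estimated correlation). They were mostly lower under each scaling (2 higher and 26 lower with quantile normalization). Fewer were lower without vitrified whole embryo 1, a fit with 1 sample left in that group. RPL24 went from 122 ± 18.1 to 59.6 ± 7.87 RPKM, RPL30 from 217 ± 22 to 91.6 ± 5.13 and RPS27A from 659 ± 97.9 to 315 ± 31.6. Nuclear genes of oxidative phosphorylation were 6 higher, 15 lower and 27 not past the threshold (camera adjusted p = 4.1e-06, and adjusted p = 0.43 with an estimated correlation, towards lower), with 3 higher and 5 lower without vitrified whole embryo 2. COX7A2 fell by 1.2 and ATP5ME by 1.11, while UQCRC1 rose by 1.15. Of the mitochondrially encoded genes 3 were higher, 2 lower and 8 not past the threshold: ND5 rose by 1.74 and MT-ND3 fell by 1.91, and their neighbours overlap. Library shares of mitochondrial messenger RNA were 4.02 ± 1.43% in vitrified and 4.23 ± 0.675% in fresh whole embryos.

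Of 42 cell cycle genes 22 were higher, 1 lower and 19 not past the threshold (camera adjusted p = 3.5e-04, and adjusted p = 0.43 with an estimated correlation), with 11 higher without vitrified whole embryo 2. The proliferation marker MKI67 went from 0.244 ± 0.0781 to 1.15 ± 0.406 RPKM and the mitotic kinase PLK1 from 1.47 ± 0.346 to 4.54 ± 1.01. Heat shock and endoplasmic reticulum stress genes were 15 higher, 1 lower and 19 not past the threshold, with 7 higher without vitrified whole embryo 2. PPP1R15A rose by 1.82, the chaperones PDIA4 and CALR by 0.94 and 0.91. Glycolysis genes were 16 higher, 0 lower and 19 not past the threshold, PKM rising by 1.36, but 2 were higher without vitrified whole embryo 2. Of 38 cytoskeleton genes 15 were higher, 2 lower and 21 not past the threshold (camera adjusted p = 0.046, and adjusted p = 0.56 with an estimated correlation), ACTB rising by 1.14 and TMSB10 falling by 1.04. 4 were higher without vitrified whole embryo 2, and the camera call was lost without it (adjusted p = 0.19) and without fresh whole embryo 2, 4 or 5 (0.057, 0.068 and 0.061), with 2.2e-04 to 0.56 over all alternatives. Chromatin genes were 14 higher, 1 lower and 17 not past the threshold, EP300 and the demethylase TET1 rising by 0.57 and 0.40, and 5 were higher without vitrified whole embryo 2.

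Fatty acid and cholesterol synthesis genes were 8 higher, 0 lower and 24 not past the threshold, the squalene synthase FDFT1 rising by 0.94 and ELOVL1 by 0.87. Junction genes were 9 higher, 2 lower and 25 not past the threshold and turned to 3 higher and 6 lower under quantile normalization and 3 and 5 under median-ratio scaling, and 4 were higher without vitrified whole embryo 2. CLDN3 rose by 2.06, DSP by 1.06 and E-cadherin (CDH1) by 0.58. Imprinted genes were 4 higher, 1 lower and 9 not past the threshold (2 higher without vitrified whole embryo 2), GNAS rising by 0.67. Matrix and protease genes had 2 higher and 2 lower members (0 higher and 3 lower with median-ratio scaling), PLAU, one of the lower, falling by 2.71. Camera placed the matrix list (0.034), nutrient transport (0.028) and blood markers (0.041) towards lower at these adjusted p. All were lost without vitrified whole embryo 2 (adjusted p = 0.19, 0.54 and 0.19), and with an estimated correlation (adjusted p = 0.55, 0.43 and 0.27). Fresh whole embryo 4 also ended each of these calls when left out (0.074, 0.062 and 0.062), and fresh whole embryo 3 that of blood markers (0.065). Over all alternatives these adjusted p ran from 0.012 to 0.95, 5.7e-04 to 0.62 and 0.016 to 0.27.

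By limma and camera, 9 lists passed, 0 with an estimated correlation and 17 with fry, and without fresh whole embryo 4 the number with camera was 5. Adjusted over the list alone, the counts of higher and lower members were 1 and 45 for ribosomal proteins, 6 and 16 for oxidative phosphorylation, 23 and 1 for cell cycle, 18 and 1 for heat shock, 17 and 1 for glycolysis, 15 and 1 for chromatin, 8 and 1 for epiblast, 5 and 1 for imprinted, 1 and 2 for matrix and 1 and 0 for nutrient transport genes, and as over all genes for the other lists named here.

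A fit over all 20 samples, with the kind of sample as a term, gave the effect of vitrification averaged over both kinds, to which the 12 TE samples contribute more than the 8 whole embryos. It does not show that both kinds changed alike. IFNT fell by 3.63 on the log2 scale, KRT8 rose by 1.98 and ASCL2 by 2.90. In total 7001 genes were higher and 650 lower (91.5% higher), against 2646 higher and 3797 lower with quantile normalization (41.1%) and 3506 higher and 2738 lower with median-ratio scaling (56.1%). Trophectoderm identity genes were 14 higher, 0 lower and 5 not past the threshold, and the list did not pass with camera (adjusted p = 0.39). Cell cycle genes were 37 higher and 1 lower (camera adjusted p = 0.0013, and adjusted p = 0.7 with an estimated correlation). Ribosomal protein genes were 14 higher and 36 lower (camera adjusted p = 1.3e-27, and adjusted p = 0.092 with an estimated correlation, towards lower). The interferon tau list was placed lower (camera adjusted p = 2.1e-04, and adjusted p = 0.034 with an estimated correlation).

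Whether the effect of vitrification differed between whole embryos and TE was tested as a difference of effects. The difference also carries whatever set the 5 fresh TE libraries apart. PAG2 changed in opposite directions, lower in TE and higher in whole embryos, and its effects differed by 5.91 (adjusted p = 2.2e-08). It stood at 61.5 RPKM in fresh TE and 1.73 in vitrified TE, and at 0.883 in fresh and 4.13 in vitrified whole embryos. Fresh TE thus lay far above the other groups. The rise in whole embryos was 0.89 on the log2 scale without vitrified whole embryo 1. PDPN rose in TE and fell in whole embryos (difference -4.16, adjusted p = 8.0e-11). For all 13 mitochondrially encoded genes the change was lower in whole embryos than in TE (camera adjusted p = 3.7e-14, and adjusted p = 0.079 with an estimated correlation), by -3.63 for COX1, -4.07 for MT-ND4 and -4.72 for MT-ND6, which lies on the strand opposite to ND5 and overlaps it. The difference was not past the threshold for ASCL2 (-0.93, adjusted p = 0.11) or GATA3 (0.21, adjusted p = 0.34). In all 3427 genes differed, 422 with a higher and 3005 with a lower effect in whole embryos (12.3% higher), against 1480 higher and 1395 lower with median-ratio scaling (51.5%) and 2064 higher and 1199 lower with quantile normalization (63.3%). The split also depended on single libraries. Without vitrified whole embryo 1, which leaves 1 sample in its group, fewer genes had a lower effect and more a higher one. Fatty acid synthesis genes were 12 higher and 3 lower in this difference (camera adjusted p = 6.6e-07, and adjusted p = 0.079 with an estimated correlation), hypoblast genes 0 and 14 (camera adjusted p = 0.0018, and adjusted p = 0.37 with an estimated correlation, towards lower). Adjusted over the list alone, higher and lower members numbered 13 and 3 and, for hypoblast genes, 0 and 18. Without vitrified whole embryo 1 the higher fatty acid genes numbered 7.

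What a fresh whole embryo holds beyond TE was addressed by 6 fresh whole embryos and 5 fresh TE samples. These 5 are the libraries that stood apart. Rank correlations of fresh whole embryos averaged 0.881 with fresh TE and 0.938 with vitrified TE. The contrast therefore also carries whatever set the fresh TE libraries apart, and not only what a whole embryo holds beyond TE. Transcripts of 4 secreted products were lower in whole embryos, at 10.8% of the TE level for IFNT, 1.44% for PAG2, 9.11% for PAG11 and 8.12% for PINLYP. The pluripotency genes POU5F1 and NANOG were higher, POU5F1 at 2.30 ± 1.87 against 0.0617 ± 0.0447 RPKM and NANOG at 0.939 ± 0.832 against 0.0206 ± 0.0324. CCL27 was 51.0-fold and PDPN 34.7-fold higher in whole embryos, and IFITM3, a membrane protein that restricts viral entry, 24.3-fold. All 13 mitochondrially encoded genes were higher, alongside mitochondrial messenger RNA shares of 4.23 ± 0.675% and 1.23 ± 0.146%. Mitochondrial ribosomal RNA went the other way, at 1.82 ± 0.697% in whole embryos and 4.28 ± 0.189% in TE (exact permutation p = 0.0043, adjusted p = 0.0096 over 20 tests, n = 6 and 5).

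In all 6364 genes were higher and 633 lower in whole embryos (91.0% higher). The split was 4116 higher and 1677 lower per M listed-gene reads (71.1%), 3181 higher and 2653 lower with median-ratio scaling (54.5%) and 2504 higher and 3675 lower with quantile normalization (40.5%), and the median gene was 2.18-fold higher as deposited, 1.39-fold per M listed-gene reads and 1.10-fold with median-ratio scaling. Fresh TE takes part in both this comparison and that of TE, so their calls share the same 5 libraries. With 6364 of 10599 genes higher, a list of mostly higher members again need not differ from other genes. Epiblast and hypoblast (adjusted p = 0.61 each), heat shock (0.46), interferon-stimulated (0.86) and water transport genes (0.97) did not pass with camera.

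Of 15 epiblast genes 10 were higher, 0 lower and 5 not past the threshold, and at least 7 were higher under each scaling. ZFP42 rose by 4.09 on the log2 scale, PDPN by 3.95 and KLF4 by 2.17. POU5F1 (adjusted p = 0.0076) and NANOG (adjusted p = 0.015) did not pass once the level of DDX3Y entered the fit (0.098 and 0.10), and NANOG missed it with the near-identical fresh TE samples averaged (0.053). DDX3Y had 0 or 1 reads in every fresh TE library, so its level largely follows these groups and may take up part of their difference. Over all alternatives their adjusted p ran from 6.6e-05 to 0.098 and 6.5e-04 to 0.1. SOX2 stood at 0.309 ± 0.216 and 0.0228 ± 0.0510 RPKM without passing. Hypoblast genes were 17 higher, 0 lower and 6 not past the threshold, the apolipoproteins APOA2, APOE and APOM rising by 4.50, 3.35 and 2.10, while GATA6 did not pass (0.01). Trophectoderm identity genes were 8 higher, 8 lower and 3 not past the threshold and turned to 5 higher and 11 lower under quantile normalization, 5 and 9 under listed-gene scaling and 5 and 10 under median-ratio scaling (camera adjusted p = 0.0025, and adjusted p = 0.091 with an estimated correlation, towards lower): GATA3 and TFAP2A fell by 0.61 and 0.91, and ID2 and KRT8 rose by 3.34 and 1.37.

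Interferon tau and other secretions were 3 higher and 5 lower (camera adjusted p = 5.2e-04, and adjusted p = 0.091 with an estimated correlation, towards lower), IFNT falling by 3.19 and PAG2 by 5.03. Of other genes that fell, the imprinted growth inhibitor CDKN1C went from 31.1 ± 10.6 RPKM in TE to 2.89 ± 1.66 in whole embryos and the defensin gene DEFB from 10.5 ± 2.27 to 0.790 ± 0.292. Fatty acid and cholesterol synthesis genes were 4 higher, 16 lower and 12 not past the threshold (camera adjusted p = 1.4e-13, and adjusted p = 0.011 with an estimated correlation, towards lower), FADS2, SCD and ELOVL5 falling by 2.12, 0.93 and 0.68. Lipid uptake genes were 13 higher, 8 lower and 9 not past the threshold and turned to 5 higher and 17 lower under quantile normalization, 7 and 14 under listed-gene scaling and 5 and 15 under median-ratio scaling. Camera placed them lower (adjusted p = 6.5e-05, and adjusted p = 0.011 with an estimated correlation) at a median of 0.02, with MOGAT1 lower by 1.23. Prostaglandin and steroid genes were 6 higher, 7 lower and 6 not past the threshold (camera adjusted p = 8.1e-04, and adjusted p = 0.037 with an estimated correlation, towards lower), PTGS2 falling by 1.36 and STAR rising by 1.19.

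Cell cycle genes were 34 higher, 1 lower and 7 not past the threshold (camera adjusted p = 0.001, and adjusted p = 0.43 with an estimated correlation), UBE2C rising by 2.67 and CDK4 by 2.5. Nuclear oxidative phosphorylation genes were 38 higher, 4 lower and 6 not past the threshold (camera adjusted p = 0.029, and adjusted p = 0.88 with an estimated correlation), with 16 higher and 15 lower under quantile normalization, and 7 lower without fresh whole embryo 4. NDUFS8 rose by 3.34. COX1 went from 679.6 ± 114 RPKM in TE to 4907 ± 704 in whole embryos and MT-CYB from 214 ± 28.6 to 2045 ± 534 (list: camera adjusted p = 1.0e-05, and adjusted p = 0.37 with an estimated correlation). Ribosomal protein genes were 31 higher, 16 lower and 27 not past the threshold and turned to 13 higher and 46 lower under quantile normalization, 14 and 41 under listed-gene scaling and 9 and 52 under median-ratio scaling, and camera placed them lower (adjusted p = 0.0033, and adjusted p = 0.88 with an estimated correlation) at a median of 0.16. Heat shock genes were 26 higher, 1 lower and 8 not past the threshold and turned to 10 higher and 14 lower under quantile normalization and 10 and 13 under median-ratio scaling, HSPA5 rising by 2.35 and HSP90AB1 by 1.30. Interferon-stimulated genes were 6 higher, 0 lower and 7 not past the threshold and turned to 3 higher and 4 lower under quantile normalization, PLAC8 rising by 2.15. Water and ion transport genes were 9 higher, 1 lower and 6 not past the threshold, AQP3 rising by 2.0, and the microtubule regulator STMN1 rose by 2.87.

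By limma and camera 9 lists passed, of which the 3 lipid lists passed with an estimated correlation. Of the 3 lists that camera placed higher, 2 kept their call with the replicate number as a block, and 2 with only the groups compared. Adjusted over the list alone, higher and lower members numbered 36 and 1 for cell cycle, 38 and 5 for oxidative phosphorylation and 6 and 8 for prostaglandin genes, and as over all genes for the other lists named here.

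In vitrified samples the same contrast rested on 2 whole embryos and 7 TE samples. IFNT and PAG2 did not differ past the threshold, IFNT standing at 86.6% of its TE level in whole embryos and PAG2 at 238% (0.89, adjusted p = 0.063, and 0.028 to 0.56 over all alternatives). NANOG (1.14, adjusted p = 0.043) and SOX2 (0.88, adjusted p = 0.032) passed as higher in whole embryos and GATA3 as lower (-0.40), but NANOG kept its call in 3, SOX2 in 10 and GATA3 in 11 of 21 alternatives. POU5F1 (1.56, adjusted p = 0.074) and GATA6 did not pass. Without vitrified whole embryo 2 NANOG stood at -0.05 and SOX2 at -0.06, and over all alternatives their adjusted p ran from 4.8e-05 to 0.95 and 5.9e-07 to 0.86, that of GATA3 from 0.035 to 0.21. Mitochondrially encoded genes were lower in whole embryos, 12 of 13. Library shares were 4.02 ± 1.43% and 8.04 ± 1.44%, without overlap (exact permutation p = 0.056, n = 2 and 7). This is the smallest p that the test can give for groups of this size.

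In all 1617 genes were higher and 381 lower (80.9% higher), against 329 higher and 266 lower with median-ratio scaling (55.3%) and 275 higher and 219 lower with quantile normalization (55.7%). Without vitrified whole embryo 2 the count was 139, with the lone sample assumed to vary like the other groups. MT-ND2 stood at 833 ± 259 RPKM in whole embryos and 2105 ± 417 in TE, and MT-ND6 at 679 ± 366 and 1764 ± 398. Without vitrified whole embryo 2 their adjusted p were 0.078 and 0.096, the highest over all alternatives, and 0 genes of the list were lower. TCEAL8 was higher in whole embryos, at 15.0 ± 1.28 against 5.57 ± 1.33 RPKM, and GLMP, a lysosomal membrane protein, lower, at 6.85 ± 0.436 against 17.7 ± 4.94 (adjusted p without vitrified whole embryo 2 = 0.054, the highest over all alternatives). UBE2V1, a ubiquitin-conjugating enzyme variant, stood at 5.25 ± 0.506 against 3.02 ± 0.459 (0.071 without that library, likewise the highest). Camera placed the mitochondrial list (adjusted p = 4.1e-14, and adjusted p = 0.13 with an estimated correlation) and 23 hypoblast genes, 5 of them lower (camera adjusted p = 9.1e-07, and adjusted p = 0.14 with an estimated correlation), towards lower in whole embryos. Of hypoblast genes 0 were lower without vitrified whole embryo 2. Matrix genes were 3 higher and 7 lower (camera adjusted p = 5.3e-06, and adjusted p = 0.14 with an estimated correlation), and 0 and 0 without that library. Of epiblast genes 6 were higher, 9 adjusted over the list alone and 0 without vitrified whole embryo 2.

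Cell cycle genes were 10 higher, 0 lower and 32 not past the threshold (camera adjusted p = 0.016, and adjusted p = 0.54 with an estimated correlation), and without vitrified whole embryo 2 the higher genes numbered 2 and the camera call was lost (adjusted p = 0.27; 0.0033 to 0.54 over all alternatives). Fatty acid synthesis (camera adjusted p = 0.024) and nutrient transport (5.3e-06) were placed lower, calls lost without that library (0.81 and 0.061) and with an estimated correlation (adjusted p = 0.53 and 0.13), with 2.7e-04 to 0.81 and 7.3e-08 to 0.13 over all alternatives. Of ribosomal protein genes 0 passed by limma (1 higher and 12 lower at an unadjusted p under 0.05), and camera placed the list lower (adjusted p = 3.4e-08, and adjusted p = 0.53 with an estimated correlation) at a median of -0.21. With camera 7 of 26 lists passed, and with an estimated correlation 0 did. With fry 12 of the 26 passed, among them 5 of the 7 in the same direction. Without vitrified whole embryo 1 the number with camera was 12. Adjusted over the list alone, higher and lower members numbered 11 and 0 for cell cycle, 3 and 10 for matrix and 0 and 4 for nutrient transport genes, and as over all genes for the mitochondrial, hypoblast, fatty acid and ribosomal lists.

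**Figure D5:**
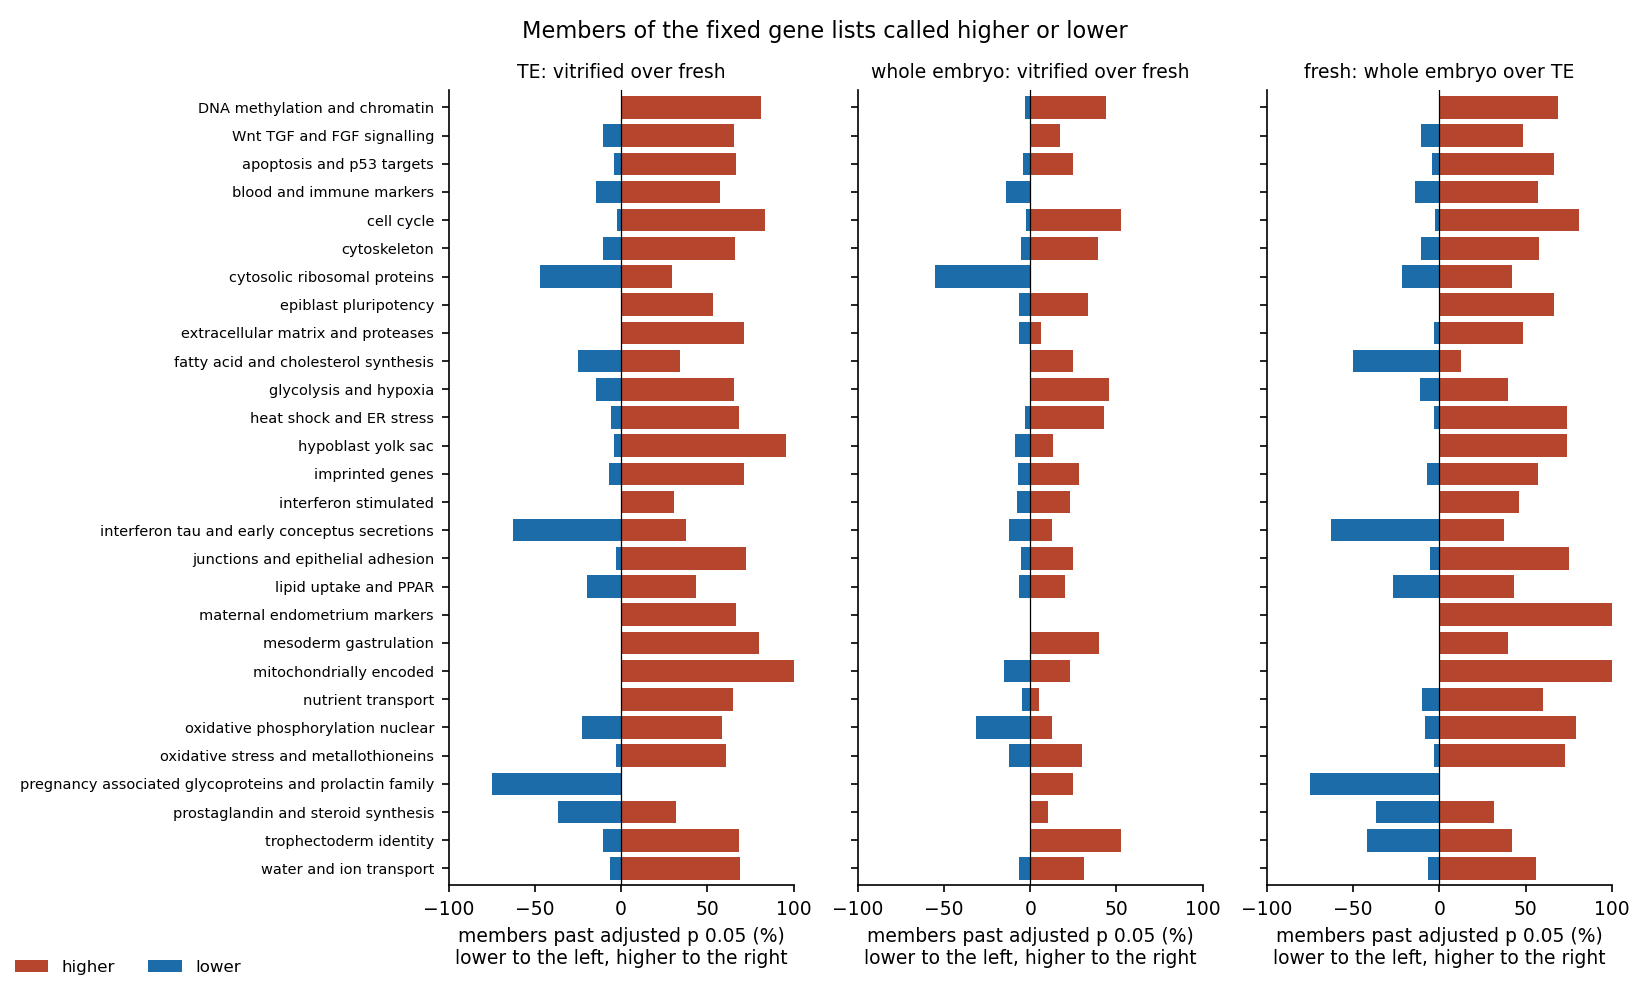
For each of 28 gene lists on the vertical axis, bars show the percent of its tested members past an adjusted p of 0.05, to the left in blue if lower and to the right in red if higher, as deposited; panels are vitrified against fresh TE, vitrified against fresh whole embryos, and fresh whole embryos against fresh TE. Ribosomal protein genes have 35, 41 and 16 of 74 members lower, and under other scalings the balance of higher and lower members turned or tied for 12, 13 and 13 of the lists, as in oxidative phosphorylation in TE with 12 higher and 28 lower under median-ratio scaling.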

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

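Tests of explanations were chosen after the result was seen, and so were splits with near-identical fresh TE averaged. The difference of effects and the other splits of the samples were set before the data were examined.

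The effect of vitrification differed between whole embryos and TE for 3427 genes, and for 10 of 19 genes named for both comparisons. The difference, whole embryo minus TE on the log2 scale, was 3.04 for IFNT, 5.91 for PAG2, 0.91 for TMSB10 and 0.96 for ATP5ME. It was -1.21 for KRT8, -4.16 for PDPN, -1.5 for PPP1R15A, -2.12 for ELOVL1, -0.70 for DSP and -2.11 for PKM. The direction was opposite in TE and whole embryos for PAG2 (-4.53 and 1.39) and PDPN (3.43 and -0.73), and the same for the other 8. For all 10 the effect was larger in TE, where the comparison rests on the fresh TE libraries that stood apart.

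The 5 fresh TE libraries stood apart in listed-gene share, mitochondrial messenger RNA and small RNA, and 8017 genes were called between vitrified and fresh TE. Scaling to listed-gene reads, which removes their lower share of reads in listed genes, gave 6878 genes, with 5918 of the 8017 called in the same direction and 33 in the opposite one. Median-ratio scaling gave 6638, with 4438 in the same and 679 in the opposite direction. The calls shared under listed-gene scaling argue against that share as the whole cause. Thinning every library to the same number of reads gave 7471, which argues against depth. Small RNA reads were 4.64-fold higher in fresh than in vitrified TE, and every fresh TE library lay above the other 15. Among these 15 were the 6 fresh whole embryos, at 68.6 to 131 small RNA reads per M listed-gene reads. Their listed-gene share was 57.5 to 61.0%. These values argue against the lack of vitrification alone as the source of this library state. Within TE, library preparation or RNA quality cannot be told apart from vitrification, with which it is confounded. The 0 or 1 reads of DDX3Y in each fresh TE library could come from 5 female embryos, or from fewer embryos than samples. DDX3X, chosen beside it, was also low in fresh TE, at 29 to 52 reads against 153 to 600 in the other 15 libraries. With the level of DDX3Y in the fit 6935 genes passed. Since that level was near 0 in every fresh TE library, this fit cannot tell sex or shared embryos apart from the group. The biological difference named by the design, vitrification itself, stays open.

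In vitrified whole embryo 1, POU5F1 had 12 reads, where the level of vitrified whole embryo 2 would give 781, which argued against too few reads. At 0.316 RPKM (0.32 rounded) POU5F1 lay within the 0.302 to 1.25 of vitrified TE, so that a TE sample and an embryo that had lost its disc may both give this value. Other values lay outside the vitrified TE libraries: mitochondrial messenger RNA at 5.03% (6.29 to 9.87% in vitrified TE) and mitochondrial ribosomal RNA at 2.0% (2.61 to 5.58%). ZFP42, of the epiblast list, stood at 74.7 RPKM, above vitrified TE (11.5 to 41.3) and fresh whole embryos (4.07 to 54.9) and near the 71.4 of vitrified whole embryo 2, so that not every gene of that list was low. Tested alone against each 6 of the vitrified TE libraries it gave 38 to 396 genes (median 88), where the remaining TE library gave 0 to 29 (median 5, SD 12.3, n = 7), fewer in each of the 7 sets, and vitrified whole embryo 2 gave 1466 to 1905. These values lean away from a TE sample like the other 7. They do not decide, since such a test of 1 library takes its spread from the other groups, the 7 sets overlap, and the lowest count, 38, exceeds the highest of TE, 29, by less than that SD, the bound set for this test. A TE sample and an embryo without its disc therefore cannot be told apart, since both would be low in POU5F1, NANOG and SOX2 and only 1 library shows the pattern. No biological explanation beyond these was tested.

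Among 100 splits of the libraries for each comparison, with the real split included, 1 gave as many genes, the real split itself. These splits count the libraries as independent, which the near-identical fresh TE libraries may not be. They also cannot exclude a batch or shared embryos that follow a group. For vitrified against fresh TE the real count was 8017 and the highest other 5735, in a split that kept the 5 fresh TE libraries together. For fresh whole embryos against fresh TE they were 6997 and 6143, in a split that put the 5 fresh TE libraries with 1 whole embryo, and for both kinds together 7651 and 5433, with all 5 fresh TE libraries in place. The median of the other splits was 0 genes, so that the highest other count of each comparison points to the structure formed by the fresh TE libraries. Which libraries were together in the further splits with high counts was not examined. With the near-identical fresh TE libraries averaged, which leaves 3 fresh TE samples, the real split alone gave as many genes in 100, 84 and 100 splits: the real counts were 7313, 6119 and 6960 and the highest others 17, 2414 and 1. The submitters' design counts 12 fresh and 9 vitrified embryos, for 11 fresh and 9 vitrified samples, which would allow an embryo for each sample, but the labels do not say whether those 3 come from 3 embryos. Splits were planned for groups of at least 3 samples, so none were run for comparisons with the 2 vitrified whole embryos alone.

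Single libraries far from the rest of their group were seen in 15 of 342 sets of gene and group tested, where chance gives about 1 in 20, or 17. Fresh whole embryo 3 had 6.01 RPKM of POU5F1 (others 1.05 to 2.29), 2.53 of NANOG (0.381 to 1.18), 1.5 of GNAS (0.916 to 1.12) and 1060 of MT-ND6 (653 to 750). Fresh whole embryo 2 had 17.9 of ELF3 (9.76 to 11.8), 1.02 of GATA3 (0.416 to 0.497) and 2.72 of UBE2V1 (3.23 to 3.47), and fresh whole embryo 1 had 3.80 of STAR (2.61 to 2.97). Vitrified TE 5 had 5.74 of IFNT (2.99 to 4.04), 0.174 of NANOG (0 to 0.0427) and 16.1 of IRF7 (6.82 to 9.26), and vitrified TE 1 had 1.06 of DNMT1 (0.807 to 0.915). Fresh TE 5 had 795 of PINLYP (394 to 481) and 18.8 of PLAC8 (13.4 to 14.8), and fresh TE 2 had 0.114 of SOX2, from 1 read, where the others had 0. No explanation was tested for these.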

How the results depend on the processing

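Alternatives were chosen before the data were examined, except scaling to listed genes, median-ratio scaling, voom, the DDX3Y covariate, averaged fresh TE and thinning, which were chosen after seeing the data. For lists, median-ratio scaling was planned, and only the groups compared and averaged fresh TE were added. A count test and a covariate for XIST were planned and not run. Where a cause is not named, the cause was not tested.

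Of 64 genes named for TE, 60 kept direction and call under every alternative, as did 40 of 45 for whole embryos, 5 of 5 for the difference, 38 of 41 for fresh whole embryos against TE and 2 of 11 for vitrified ones. GATA3 in TE reversed to -0.03 with quantile normalization. Without a library in turn, NANOG ran from -0.05 to 2.33 and SOX2 from -0.06 to 1.82 in vitrified whole embryos against TE.

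Of genes called in TE, 679 had the opposite call with median-ratio scaling and 1421 with quantile normalization. Counts of genes stayed within 1.5 times of those reported under each alternative for vitrified against fresh TE, both kinds, the difference and fresh whole embryos against TE, except with at least 5 RPKM, where 2087 or 2380 genes were tested: 1784, 1906, 1391 and 1766, with 841 for vitrified against fresh whole embryos and 321 for vitrified whole embryos against TE. These last comparisons, each with a group of 2, gave 1571 and 494 with quantile normalization, 1864 and 595 with median-ratio scaling, 1763 and 175 with sample weights, and 2157 and 786 with only the groups compared. The second gave 1075 with the DDX3Y covariate. Leaving out a library gave 1137 to 3577 and 139 to 2329, where a lone sample left in a group was assumed to vary like the other groups, and 7724 to 7982 for TE.

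With the replicate number as a block the count in vitrified whole embryos against TE was 790. Of 22 pairs of libraries with the same number 7 correlated above 0.1 (-0.19 to 0.38). Of these, 5 lay among the 6 pairs of a fresh whole embryo with vitrified TE, with a mean of 0.161 (-0.026 for pairs with different numbers) and a lowest of -0.136. Since not every pair passed 0.1 in any combination with 3 or more, and the labels name no shared animal, the numbers were not taken as pairs.

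Lists past the threshold numbered 2, 0, 3, 0, 3 and 0 with an estimated correlation (TE, whole embryos, both kinds, difference, fresh and vitrified whole embryos against TE) and 23, 17, 24, 22, 24 and 12 with fry, which tests each list by itself. For whole embryos they numbered 5 with listed-gene and 4 with median-ratio scaling, and 5 to 12 without a library, and for vitrified whole embryos against TE 6 to 12. Fry reversed the direction of the fatty acid list in TE (adjusted p = 0.039) and both kinds (0.0015), of the lipid uptake (8.7e-05) and prostaglandin (0.0066) lists in both kinds, and of ribosomal proteins in fresh whole embryos against TE (0.0058), since it does not compare a list with other genes. Depth limits genes near 0, such as SOX2 at 0 to 10 reads in fresh whole embryos.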

Other observations

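The tests of ribosomal protein genes, and the choice of which genes to set side by side, were made after the results were seen. The tests of each gene were set before the data were examined.

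The immediate early gene FOS stood at 9.56 ± 7.74 RPKM in fresh and 61.6 ± 18.8 in vitrified whole embryos, and at 9.82 ± 1.57 and 41.6 ± 15.6 in fresh and vitrified TE (difference of effects 0.91, adjusted p = 0.26). PPP1R15A, which ends the stress block of translation, stood at 1.66 ± 0.710 and 8.23 ± 2.04 in whole embryos and 0.261 ± 0.127 and 11.8 ± 3.1 in TE. The plasminogen activator PLAU was high in fresh whole embryos alone, at 68.8 ± 22.1 RPKM against 9.75 ± 4.69 in vitrified ones and 5.47 ± 2.80 and 8.08 ± 4.52 in fresh and vitrified TE (difference -3.16, adjusted p = 5.7e-04). The chemokine CCL27 (-5.92, adjusted p = 2.2e-04) and BHLHE40, a repressor linked to low oxygen and the clock (-2.15, adjusted p = 0.0011), had the same arrangement.

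Ribosomal protein genes were lower in vitrified whole embryos for 41 of 74 genes. Without vitrified whole embryo 1, a fit with 1 sample left in that group, fewer were lower. The lowest number under another scaling was 26, which argues against scaling as the whole cause. A candidate explanation is a difference between libraries that also runs among fresh embryos: across the 74 genes, which are not independent replicates, the first component among the 6 fresh whole embryos correlated with the fold change of TE, from other libraries, at an absolute Spearman rho of 0.81 (0.77 to 0.81 without a library), and the fold changes of TE and whole embryos at 0.87. For the first component among fresh TE libraries rho was 0.41 and among vitrified TE libraries 0.08. Over all genes tested it was 0.45 among fresh whole embryos, with 0.53 between the fold changes. For 1817 genes with a mean of at least 5 RPKM it was 0.63 among fresh whole embryos, 0.07 among fresh TE and 0.21 among vitrified TE libraries. The relation among fresh whole embryos was thus not limited to ribosomal protein genes, and it was not seen in every group. Each whole embryo was also placed along the fold change of TE across these genes, relative to the mean of the fresh whole embryos. The vitrified ones lay at 0.31 and 0.34 and the fresh ones at -0.26 to 0.14. Since the fold changes of TE and whole embryos go together at 0.87, vitrified embryos had to lie on the positive side, so these places do not decide a cause. Vitrification may have moved embryos along an axis on which fresh ones also vary, or the axis may be technical. Positions of the 6 fresh whole embryos correlated with their listed-gene share (Pearson r = 0.86, exact permutation p = 0.036; Spearman rho = 0.89, exact permutation p = 0.033; r = 0.70 without the 2 farthest), short of the threshold after adjustment over 3 relations (exact permutation, adjusted p = 0.08). With library reads r was 0.83 (exact permutation p = 0.053, adjusted p = 0.08) and with mitochondrial messenger RNA -0.35 (exact permutation p = 0.5), and a technical axis stays open.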
